A study of Mus musculus with 9 samples.

How the data were processed

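Gene expression was measured by RNA-seq in 9 libraries of mouse bone marrow-derived dendritic cells, 3 untreated, 3 after 2 h of lysophosphatidic acid (LPA) and 3 after 6 h. Per the labels' protocols, total RNA was purified with the RNeasy MinElute kit, and mRNA libraries were made with a non-stranded TruSeq protocol. Because such libraries do not keep the strand, reads of a gene and of a gene overlapping it on the opposite strand cannot be told apart.

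The authors deposited 1 table of estimated counts per gene for all 9 libraries, rounded to whole numbers and not scaled for depth. Per the submitters' processing notes, RSEM 1.2.3, DESeq2 and the genome build mm10 were used. RSEM divides reads that match several transcripts among them, so counts of near-identical genes depend on that division. The aligner and the annotation release are not given in the sources used here. Each of the 38887 rows named its gene by a list of Ensembl transcript identifiers. These were matched to genes of the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, from which symbols and coordinates were taken. Of these rows 37776 matched 1 gene and held 98.46% of the counts, 176 matched several genes and held 1.4%, and 935 matched none and held 0.14%. For 210 genes more than 1 row was found. There were 0 rows on the mitochondrial chromosome, so the fixed list of mitochondrially encoded genes could not be measured.

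Totals ran from 29628817 to 84596899 counts per library. Replicates were compared before use, and counts of replicate pairs differed by 7.3 to 33.7 chi-square units per degree of freedom, so none was a repeat of another. For 6 h against untreated, deviations of same-numbered libraries from their group means correlated at 0.14 to 0.18, over the limit of 0.1 in all 3 pairs, so there the replicate numbers were taken to pair the libraries. The pairing comes from the data, since the labels give only the numbers. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 14363. Libraries were scaled with TMM factors, which ran from 0.974 to 1.03. All 9 libraries were fitted together with edgeR 4.0.16 (glmQLFit with robust = TRUE and glmQLFTest, R 4.3.3), with a mean for each group and no covariate. The pairing at 6 h was thus not used in the main fit, and the replicate number entered only in an alternative. The common biological coefficient of variation was 0.075. The comparisons were 2 h against untreated, 6 h against untreated, and 6 h against 2 h, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM values used the TMM-scaled library sizes, and SD is over the 3 libraries of a group.

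Gene lists were fixed before the data were examined: 16 pathway lists, 10 lists of cell type markers and 2 lists on RNA quality. The 27 lists with at least 3 tested members were tested in the 3 comparisons with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 81 tests, and again with an estimated correlation and with fry. None of the 19 camera calls passed with the estimated correlation. Genes were named by a rule fixed at the same stage: per comparison with untreated, the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group, separated groups and an established symbol (4 and 4 between the times); per pathway list the 2 members with the smallest p, 4 for the interferon-stimulated and prostaglandin lists (1 between the times); and always Ifnb1, Ifnar1, Cxcl10, Ptgs2, Ptges, Lpar1 to Lpar6, Vegfa and Il10.

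The tests were checked on simulated counts for 14228 genes, of which 197 at 2 h, 199 at 6 h and 396 between the times had known changes. At 2 h against untreated, 67.2%, 89.1% and 97% of genes changed 1.5-fold, 2-fold and 4-fold were called in the right direction, and 9.8% of calls were unchanged genes. At 6 h against untreated the shares were 85.1%, 81.8% and 97%, with 8.4% of calls unchanged, and between the times 76.1%, 82.3% and 95.5%, with 6.4% unchanged. The shares of unchanged genes were above the 0.05 that the adjustment aims at. Far more genes were called in the data than were changed here, so these shares need not carry over. Camera gave a p under 0.05 for 3 of 100 random lists. The simulated genes were drawn independently, so this does not check the preset correlation for correlated lists. The estimated correlation was 0.641 for interferon-stimulated genes and 0.568 for cholesterol synthesis genes. Changes under 1.5-fold, and genes near the filter, were not checked separately and may be resolved less well.

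Alternatives fixed before the data were examined were DESeq2 size factors, total counts only and upper quartile scaling, DESeq2 1.42.0 and limma-voom as tools, no filter or a mean of at least 10 counts, the replicate number as a block, only the 6 libraries compared, a test against a 1.5-fold change (glmTreat), an adjusted p of 0.01, a fit without robust dispersion, and leaving out each library in turn. Thinning all libraries to the smallest total was added after seeing the data. The position of each 2 h library between its group and the 6 h libraries, and non-negative least squares fits of each library on the other 8 (scipy 1.17.1, numpy 2.4.6), were also added after seeing the data. The least squares step recovered a share of 0.4 from a simulated mixture made with 0.4. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.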

Results

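RNA-seq was carried out on mouse bone marrow-derived dendritic cells (BMDC), antigen-presenting cells grown in culture from bone marrow precursors. Cells were left untreated or were exposed to lysophosphatidic acid (LPA), a signalling phospholipid that acts through G protein-coupled receptors, for 2 h or 6 h. The series title places the experiment in work on how LPA released by ovarian tumors affects type I interferon responses. Each of the 3 groups held 3 libraries. Estimated counts totalled 47425282, 66798287 and 47724259 in the untreated libraries, 57519390, 84596899 and 47202425 at 2 h, and 29628817, 54067138 and 63050458 at 6 h. After filtering, 14363 genes were tested in all 9 libraries. The labels give no LPA dose, no vehicle and no time point for the untreated cells. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

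The 3 groups separated on the principal components of log2 CPM (read counts scaled to equal library totals), with 46.2% of the variance on PC1 and 23.4% on PC2. Untreated libraries lay between -36.9 and -34.5 on PC1 and the 6 h libraries between 35.7 and 40.6. The 2 h libraries were spread more widely, from -12.4 to 9.7. Replicate 2 at 2 h, the deepest library, was the outlying library of its group. Over 386 genes that differed at least 2-fold between the times, it lay a median of 0.393 of the way from the other 2 h libraries to the 6 h libraries (95% interval over genes 0.385 to 0.405).

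**Figure D1:**
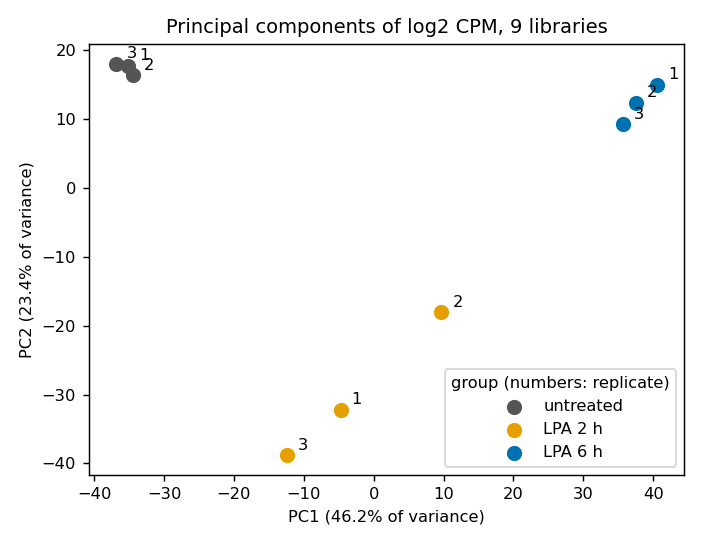
Principal components of log2 CPM for the 9 libraries, PC1 on the x axis and PC2 on the y axis, with the replicate number beside each point. Untreated and 6 h libraries form tight clusters at opposite ends of PC1, and replicate 2 at 2 h lies at 9.7 on PC1, between the other 2 h libraries and the 6 h libraries.

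The response at 2 h was examined by comparing the 2 h libraries with the untreated ones. At 2 h, 35 of 47 interferon-stimulated genes and 19 of 24 cholesterol synthesis genes were lower, and 24 of 35 immediate early and cAMP-response genes were higher and 7 lower. Camera called these lists at its preset correlation but not with an estimated one (adjusted p from 0.508 to 0.564). Hilpda, which encodes a lipid droplet protein that inhibits triglyceride breakdown, rose from 9.43 ± 0.878 to 316.7 ± 24.6 CPM (mean ± SD, n = 3 each). Vegfa, the main angiogenic growth factor gene, rose from 25.8 ± 2.66 to 246 ± 24.4 CPM. Tnf, a central inflammatory cytokine, fell from 19.98 ± 1.52 to 3.22 ± 1.22 CPM. Ciita, the master regulator of MHC class II transcription, fell from 80.6 ± 3.04 to 22.1 ± 1.66 CPM.

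In total 5525 genes changed at 2 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 2768 of them higher and 2757 lower. Of these, 413 were at least 2-fold higher and 209 at least 2-fold lower. In 48.2% of tested genes every library of one group lay above every library of the other, where chance gives 10%. The 6 largest rises selected by the naming rule were Fosb (log2 fold change 6.46 ± 0.43, SE), a component of the AP-1 transcription factor, Fam71f2 (5.31 ± 0.20), Hilpda (5.06 ± 0.08), Trem1 (4.25 ± 0.21), an activating receptor of myeloid cells, Lepr (4.0 ± 0.50), the leptin receptor, and Angptl4 (3.73 ± 0.37), a secreted inhibitor of lipoprotein lipase. Fam71f2 (chromosome 6, 29279593 to 29290680, GRCm38) begins just after Hilpda (chromosome 6, 29272488 to 29275446) on the same strand, so reads running on from Hilpda cannot be told apart from Fam71f2 transcripts. The 6 largest falls were F3 (-3.05 ± 0.16), which encodes tissue factor, Tnf (-2.59 ± 0.21), Npas4 (-2.47 ± 0.14), Kcnj2 (-2.42 ± 0.11), a potassium channel gene, Klf2 (-2.09 ± 0.20) and the olfactory receptor gene Olfr111 (-2.05 ± 0.16), whose counts are uncertain because it has close paralogs. Adjusted p for these 12 genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ran from 1.41e-12 for Hilpda to 8.82e-04 for Lepr, and in each gene all 3 treated libraries lay on one side of all 3 untreated libraries.

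Of the 47 tested interferon-stimulated genes, 35 fell at 2 h and 0 rose, with a median log2 fold change of -0.62. Adjusted over the list alone, 37 fell. Camera gave the list an adjusted p of 8.24e-12, and adjusted p = 0.564 with an estimated correlation. Usp18, a negative regulator of interferon receptor signalling, fell by 1.21 ± 0.08 on the log2 scale, the interferon signalling factor Stat2 by 0.78 ± 0.06, the antiviral GTPase gene Mx1 by 0.92 ± 0.07 and Tor3a by 0.66 ± 0.05. The chemokine gene Cxcl10 had a log2 fold change of -0.62 ± 0.25 and did not pass the test (adjusted p = 0.0789, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without untreated replicate 1 it passed at -0.82, and without 2 h replicate 3 at -0.90, and it also passed with limma-voom and with the replicate number as a block. Among 22 tested genes of type I interferon induction, 13 fell and 4 rose, the same counts as adjusted over the list alone (camera adjusted p = 0.0304, and adjusted p = 0.508 with an estimated correlation). The kinase gene Ikbke (-0.75 ± 0.05) and the DNA sensor gene Cgas (-0.73 ± 0.07) were among those that fell. Ifnar1, which encodes a chain of the type I interferon receptor, was 172.5 ± 1.18 CPM untreated and 176 ± 4.21 CPM at 2 h, a log2 fold change of 0.03 ± 0.04 that did not pass the test.

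Immediate early and cAMP-response genes were mostly higher at 2 h: 24 of 35 rose and 7 fell, and adjusted over the list alone 24 rose and 8 fell. Camera gave an adjusted p of 2.9e-05, and adjusted p = 0.508 with an estimated correlation. The circadian regulator Per1 rose by a log2 fold change of 1.39 ± 0.08 and the salt-inducible kinase gene Sik1, a known CREB target, by 1.84 ± 0.10, while Klf2 fell. Cholesterol synthesis and LDL uptake genes moved the other way, with 19 of 24 lower and 0 higher, or 20 lower adjusted over the list alone (camera adjusted p = 2.89e-06, and adjusted p = 0.564 with an estimated correlation). Hmgcs1, an early enzyme of the mevalonate pathway, fell from 269.7 ± 19.7 to 158 ± 5.86 CPM, and Fdft1, which encodes squalene synthase, fell by 0.78 ± 0.06 on the log2 scale. Of 22 SRF/MRTF and YAP target genes, 12 fell and 3 rose, or 13 and 4 adjusted over the list alone, with Fhl3 at -0.79 ± 0.07 and Cnn2 at -0.39 ± 0.04. Camera called this list at an adjusted p of 0.0408, and adjusted p = 0.628 with an estimated correlation. That call was lost without untreated replicate 2 (0.1), without 2 h replicate 2 (0.0967), with the replicate number as a block (0.0563) and with all libraries thinned to equal depth (0.0771).

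The remaining pathway lists were not called by camera at 2 h. In the prostaglandin and eicosanoid list 4 of 20 genes rose and 6 fell, or 5 and 7 adjusted over the list alone. Ptgs2 (chromosome 1, 150100031 to 150108227), which encodes the inducible cyclooxygenase COX-2, rose from 3.42 ± 0.361 to 13.4 ± 3.26 CPM, a log2 fold change of 1.95 ± 0.17. The prostacyclin receptor gene Ptgir fell from 227 ± 4.90 to 95.6 ± 12.5 CPM, and the prostaglandin E2 receptor genes Ptger4 (-0.64 ± 0.06) and Ptger1 (-0.29 ± 0.05) also fell. Ptges, which encodes an inducible prostaglandin E synthase, was 10.7 ± 0.551 CPM untreated and 11.6 ± 0.505 CPM at 2 h and did not pass the test. Of 12 tested genes of LPA receptors and metabolism 4 rose and 1 fell. Lpar1 (chromosome 4, 58435255 to 58553898) rose from 2.84 ± 0.0160 to 25.1 ± 5.22 CPM and P2ry10 by a log2 fold change of 0.81 ± 0.08. Lpar6, the most abundant LPA receptor transcript, rose by 0.25 ± 0.05, Lpar5 fell by 1.19 ± 0.12, and Lpar2 (-0.17 ± 0.15) and Lpar3 (-0.05 ± 0.20) did not pass.

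Inflammatory cytokine and chemokine genes went both ways at 2 h, with 7 of 27 higher and 9 lower, or 7 and 11 adjusted over the list alone. The monocyte chemoattractant gene Ccl2 (-1.92 ± 0.14) and Ccl3 (-1.81 ± 0.13) fell with Tnf. Among 25 immunoregulatory and angiogenic genes 8 rose and 4 fell, with the smallest p for the cytokine gene Osm (3.30 ± 0.11) and Vegfa (3.25 ± 0.13). In the MHC class II and co-stimulation list 7 of 20 rose, among them the co-stimulatory gene Cd80 (0.65 ± 0.07), and 3 fell, among them Ciita (-1.87 ± 0.06). In the MHC class I list 4 of 17 fell and 0 rose, with the class I transactivator Nlrc5 at -0.53 ± 0.06 and the peptide transporter gene Tap2 at -0.32 ± 0.04. Camera called that list only without 2 h replicate 1 (adjusted p = 0.0356, and 0.0932 with all libraries). Of 18 genes of LXR targets and lipid export 11 fell and 4 rose, or 12 and 4 adjusted over the list alone. The fatty acid synthase gene Fasn fell by 1.30 ± 0.06 and the cholesterol exporter gene Abca1 rose by 0.89 ± 0.08. In the unfolded protein response list 7 of 25 rose, among them Trib3 (1.76 ± 0.15) and Atf4 (0.56 ± 0.06), and 5 fell. In the glycolysis and hypoxia list 6 of 23 rose, among them the lactate exporter gene Slc16a3 (0.66 ± 0.08), and 3 fell, among them Hk2 (-0.49 ± 0.05). For cell cycle genes 8 of 26 fell, among them Ccnd1 (-1.16 ± 0.12), and 4 rose, among them Cenpa (0.81 ± 0.08). For lysosome and phagocytosis genes 3 of 24 fell, among them the lysosomal regulator Tfeb (-1.0 ± 0.09), and 2 rose, among them Ctsl (0.21 ± 0.05). In the lists of this and the preceding paragraph for which no separate count is given, the counts adjusted over the list alone were the same. Median, mean and camera direction differed in sign at 2 h for the LPA receptor list (-0.04, 0.27, up), MHC class II (-0.01, -0.03, up), unfolded protein response (-0.04, 0.15, up), lysosome (0.03, -0.02, up), macrophage marker (0.01, -0.01, down) and stromal marker (-0.05, 0.15, up) lists. Without 2 h replicate 2, 5580 genes changed at 2 h and 35 interferon-stimulated genes were lower.

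**Figure D2:**
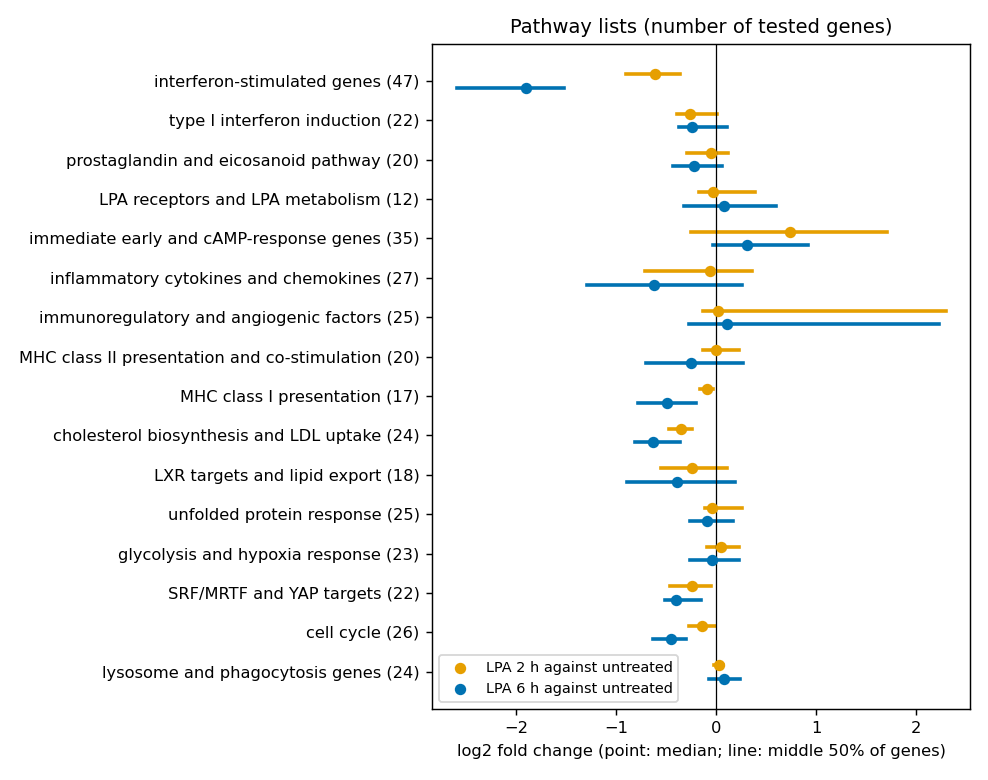
Log2 fold changes against untreated cells for the 16 pathway lists at 2 h (orange) and 6 h (blue), with the point at the median of the tested genes and the line over the middle 50% of them. The interferon-stimulated genes lie lowest, at a median of -0.62 at 2 h and -1.91 at 6 h.

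The response at 6 h was examined in the same way against the untreated libraries. At 6 h all 47 tested interferon-stimulated genes were lower, 20 of them by more than 4-fold. Most tested MHC class I, cholesterol synthesis, cell cycle and inflammatory cytokine genes were lower too, with 6 of 27 cytokine genes higher, and camera called these lists at its preset correlation but not with an estimated one (adjusted p = 0.508 for each). Ifit3, an interferon-induced antiviral gene, fell from 60.9 ± 1.16 to 3.16 ± 0.256 CPM (mean ± SD, n = 3 each). Nt5e, which encodes the ecto-enzyme CD73 that produces adenosine, rose from 9.76 ± 1.12 to 161 ± 2.92 CPM. Angptl4 rose from 3.58 ± 0.736 to 113 ± 1.51 CPM, and Hilpda reached 357 ± 9.30 CPM.

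At 6 h 7472 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 3786 higher and 3686 lower, with 496 at least 2-fold higher and 644 at least 2-fold lower. In 63.0% of tested genes the libraries of the groups did not overlap, against 10% by chance. The 6 largest rises selected by the naming rule were Hilpda (5.24 ± 0.08), Lepr (5.16 ± 0.49), Angptl4 (4.99 ± 0.37), the coagulation factor gene F5 (4.08 ± 0.27), Nt5e (4.05 ± 0.37) and Snph (3.78 ± 0.18). The 6 largest falls selected by the same rule were all interferon-inducible genes: Ifit3b (-4.86 ± 0.34), Ifit3 (-4.27 ± 0.22), Ifi44 (-3.94 ± 0.29), Ifit2 (-3.91 ± 0.29), Ifit1 (-3.88 ± 0.17) and Ifi213 (-3.84 ± 0.20). Ifit3 (chromosome 19, 34583531 to 34588731) and Ifit3b (34607970 to 34613401) are close copies, as are Ifi213 and its neighbours, so the division of reads among such copies is uncertain. Adjusted p for these 12 genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ran from 1.015e-12 for Hilpda to 1.57e-04 for Lepr, with all 3 treated libraries on one side of all 3 untreated libraries in each.

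All 47 tested interferon-stimulated genes fell at 6 h, with a median log2 fold change of -1.91 and the same count adjusted over the list alone. Camera gave an adjusted p of 4.92e-25, and adjusted p = 0.508 with an estimated correlation. The fall was -1.91 ± 0.07 in Mx1, -2.96 ± 0.13 in Mx2, -2.00 ± 0.08 in Usp18 and -1.81 ± 0.08 in Phf11d. Cxcl10 fell from 3.60 ± 1.02 to 0.231 ± 0.0494 CPM. Type I interferon induction genes included 13 of 22 lower and 5 higher, or 14 and 5 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0932). Ikbke fell by 0.79 ± 0.05, and the row holding the DNA exonuclease gene Trex1, which also matches another gene, fell by 1.94 ± 0.08. Ifnar1 stayed at 171 ± 3.36 CPM, a log2 fold change of -0.01 ± 0.04. Ifnb1, which encodes interferon beta, was below the filter, with 5, 2 and 0 counts untreated, 2, 5 and 1 at 2 h and 0 in each 6 h library, too few to show a difference. Il10 and Lpar4 were also below the filter.

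**Figure D3:**
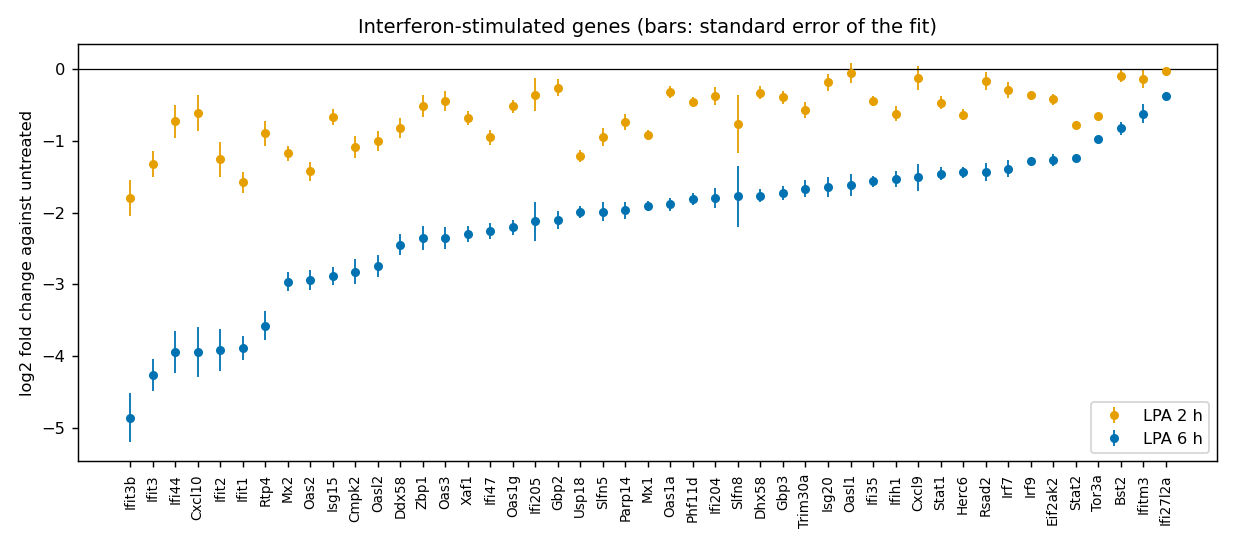
Log2 fold change against untreated cells for each of the 47 tested interferon-stimulated genes at 2 h (orange) and 6 h (blue), with bars for the standard error of the fit. The 6 h values lie below 0 for all 47 genes, from -4.86 in Ifit3b to -0.39 in Ifi27l2a.

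In the MHC class I list 14 of 17 genes fell at 6 h and 1 rose (camera adjusted p = 1.09e-04, and adjusted p = 0.508 with an estimated correlation). Nlrc5 fell from 95.1 ± 2.69 to 32.7 ± 0.339 CPM and the proteasome activator gene Psme2 by 1.05 ± 0.07 on the log2 scale. In the MHC class II and co-stimulation list 11 of 20 fell and 6 rose, with Ciita at -2.13 ± 0.07 and Cd80 at 0.82 ± 0.07, and camera did not call the list (adjusted p = 0.128). Cholesterol synthesis and LDL uptake genes had 23 of 24 lower and 0 higher, with a median of -0.63 (camera adjusted p = 3.78e-08, and adjusted p = 0.508 with an estimated correlation). Among them the mevalonate kinase gene Mvk fell by 1.14 ± 0.07 and Fdft1 by 0.95 ± 0.06. Cell cycle genes had 21 of 26 lower and 1 higher (camera adjusted p = 3.4e-05, and adjusted p = 0.508 with an estimated correlation). Ccnd1, which encodes cyclin D1, fell from 20.5 ± 1.04 to 3.70 ± 0.247 CPM, and the gene that rose was Cenpa, a centromeric histone gene (1.10 ± 0.08). SRF/MRTF and YAP target genes had 14 of 22 lower and 2 higher, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00532, and adjusted p = 0.508 with an estimated correlation). The beta-actin gene Actb fell by 0.77 ± 0.07 and the receptor kinase gene Axl by 0.75 ± 0.06.

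Inflammatory cytokine and chemokine genes had 18 of 27 lower and 6 higher at 6 h (camera adjusted p = 0.0129, and adjusted p = 0.508 with an estimated correlation). Ccl2 fell by 2.75 ± 0.16, while the cytokine gene Lif rose by 1.71 ± 0.12. In the prostaglandin and eicosanoid list 12 of 20 fell and 3 rose (camera adjusted p = 0.0459, and adjusted p = 0.508 with an estimated correlation), a call that was lost without untreated replicate 2 (0.0546) and with the replicate number as a block (0.0579). The 5-lipoxygenase gene Alox5 fell by 1.2 ± 0.09, the thromboxane synthase gene Tbxas1 by 0.56 ± 0.06, Ptgir by 0.81 ± 0.08 and the constitutive cyclooxygenase gene Ptgs1 by 0.43 ± 0.06. Ptgs2 was 3.04 ± 0.361 CPM at 6 h, a log2 fold change of -0.18 ± 0.18 that did not pass the test, and Ptges fell by 0.44 ± 0.07. Immediate early and cAMP-response genes had 21 of 35 higher and 5 lower (camera adjusted p = 0.0129, and adjusted p = 0.508 with an estimated correlation), with the cAMP-responsive repressor gene Crem at 1.73 ± 0.12 and the cAMP phosphodiesterase gene Pde4d at 1.16 ± 0.08.

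Camera did not call the other pathway lists at 6 h. LPA receptor and metabolism genes had 5 of 12 higher and 3 lower, with Lpar6 at 0.41 ± 0.05, Lpar1 at 1.26 ± 0.16, Lpar5 at -0.38 ± 0.11 and Plpp1, which encodes a phosphatase that degrades LPA, at -1.39 ± 0.13. Lpar2 (-0.00 ± 0.16) and Lpar3 (-0.31 ± 0.20) did not pass. Immunoregulatory and angiogenic genes had 10 of 25 higher and 8 lower, with Osm at 2.45 ± 0.11, Vegfa at 2.72 ± 0.12 and the matrix protease gene Mmp14 at -0.61 ± 0.04. LXR target and lipid export genes had 11 of 18 lower and 5 higher, with the lipoprotein lipase gene Lpl falling from 5467 ± 170.2 to 2287 ± 58.6 CPM and Fabp4 by 1.30 ± 0.08. Unfolded protein response genes had 7 of 25 higher and 8 lower, with Dnajb9 at 0.49 ± 0.05 and Sec61b at -0.51 ± 0.06. Glycolysis and hypoxia genes had 5 of 23 higher and 9 lower, with Ldha at 0.43 ± 0.05 and Hk2 at -0.44 ± 0.05. Lysosome and phagocytosis genes had 9 of 24 higher and 5 lower, with Ctsl at 0.50 ± 0.05 and Laptm5 at 0.35 ± 0.05. At 6 h, where no separate count is given, the counts adjusted over the list alone were the same. Median, mean and camera direction differed in sign at 6 h for the LPA receptor (0.08, -0.03, up), T and NK marker (-0.46, -0.28, up), stromal marker (-0.28, 0.12, down) and histone and nuclear RNA (-0.11, 0.55, down) lists. Without 2 h replicate 2 in the shared fit, 7896 genes changed at 6 h and 47 interferon-stimulated genes were lower.

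Marker genes of other cell types were measured in the same libraries, and camera called none of the 10 marker lists at either time. Conventional dendritic cell markers had 1 of 13 higher and 3 lower at 2 h, and 2 higher and 6 lower at 6 h. Macrophage and monocyte markers had 2 of 16 higher and 4 lower at 2 h, and 4 higher and 8 lower at 6 h. Neutrophil markers had 0 of 11 higher and 1 lower at 2 h, and 5 lower at 6 h. T and NK cell markers had 2 of 6 higher at 2 h, and 3 higher and 3 lower at 6 h. Their summed CPM rose from 589 ± 16.6 untreated to 748 ± 48.8 at 2 h and 975.2 ± 15.9 at 6 h, nearly all of it from Il7r, at 586, 745 and 972 CPM. B and plasma cell markers had 0 of 3 called at 2 h and 1 lower at 6 h, which was the immunoglobulin gene Ighm (-2.63 ± 0.20). Their summed CPM fell from 11.6 ± 1.45 untreated to 9.13 ± 2.21 at 2 h and 2.41 ± 0.0984 at 6 h, most of it from Ighm. Changes were also counted in plasmacytoid dendritic cell markers, 2 of 7 higher at 2 h and 3 lower at 6 h, and in mast cell and basophil markers, 1 of 3 higher at 2 h and 1 in each direction at 6 h. Erythroid and megakaryocyte markers had 3 of 5 higher at 2 h and 1 in each direction at 6 h, and eosinophil markers 0 of 4 called at 2 h and 2 lower at 6 h. Stromal markers had 1 of 7 higher at 2 h, which was Lepr, and 2 in each direction at 6 h. The list of histone and nuclear RNAs that escape poly(A) selection had 1 of 10 in each direction at 2 h and 2 lower at 6 h. Adjusted over the list alone, the counts differed for 0 neutrophil genes lower, 2 T and NK genes lower and 2 mast cell genes higher, all at 2 h.

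The change between the time points was tested directly by comparing the 6 h with the 2 h libraries. This is also the test of whether the 2 changes from untreated differ. It cannot tell LPA apart from time in culture, since the untreated cells have no time point in the labels. Between 2 h and 6 h interferon-stimulated genes fell further, while genes with an early peak, such as Fosb, Ptgs2 and Lpar1, came down. Fosb fell from 37.2 ± 13.4 CPM at 2 h to 1.64 ± 0.457 at 6 h. Ptgs2 fell from 13.4 ± 3.26 to 3.04 ± 0.361 CPM and Lpar1 from 25.1 ± 5.22 to 6.84 ± 0.547 CPM (mean ± SD, n = 3 each).

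In this comparison 6991 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 3493 higher and 3498 lower at 6 h, with 164 at least 2-fold higher and 492 at least 2-fold lower. Without 2 h replicate 2 these were 326 and 597. Libraries of the groups did not overlap in 58.9% of tested genes, against 10% by chance. The 4 largest falls selected by the naming rule were Fosb (-4.43 ± 0.36), Ifi44 (-3.21 ± 0.30), Ifit3 (-2.95 ± 0.22) and the interferon-inducible gene Rtp4 (-2.68 ± 0.20). The 4 largest rises selected by the same rule were Bach2 (1.94 ± 0.44), a transcriptional repressor gene of lymphocytes, Edil3 (1.76 ± 0.44), Rims3 (1.72 ± 0.49) and Plcb1 (1.69 ± 0.25). Replicate 2 had the highest level of these 4 genes among the 2 h libraries, and without it Bach2 rose by 2.86, Edil3 by 2.62 and Rims3 by 2.69. The Rims3 call (adjusted p = 0.0229, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) was lost without 2 h replicate 1 (0.0565) and without any of the 6 h replicates (0.0556, 0.053 and 0.0508), with no filter (0.0509) and with only the 6 libraries compared (0.0605). Adjusted p for the other 7 of these genes, by the same edgeR test and adjustment, ran from 4.29e-05 for Rtp4 to 0.0148 for Edil3.

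Of 47 interferon-stimulated genes 46 were lower at 6 h than at 2 h and 0 higher, with a median of -1.42 (camera adjusted p = 9.77e-23, and adjusted p = 0.508 with an estimated correlation). Phf11d fell by 1.35 ± 0.08 and Cxcl10 by 3.33 ± 0.36. MHC class I genes had 11 of 17 lower and 0 higher (camera adjusted p = 2.23e-04, and adjusted p = 0.508 with an estimated correlation), with Nlrc5 at -1.01 ± 0.07. MHC class II and co-stimulation genes had 11 of 20 lower and 1 higher, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0214, and adjusted p = 0.564 with an estimated correlation), with H2-DMb1 at -1.10 ± 0.09. Cell cycle genes had 18 of 26 lower and 2 higher, or 19 and 2 adjusted over the list alone (camera adjusted p = 1.41e-04, and adjusted p = 0.508 with an estimated correlation), with the thymidine kinase gene Tk1 at -0.58 ± 0.07. Immediate early and cAMP-response genes had 21 of 35 lower and 6 higher, or 22 and 7 adjusted over the list alone (camera adjusted p = 0.00881, and adjusted p = 0.508 with an estimated correlation), with Junb at -1.51 ± 0.09. Cholesterol synthesis genes had 11 of 24 lower and 1 higher (camera adjusted p = 0.0205, and adjusted p = 0.719 with an estimated correlation), with Mvk at -0.77 ± 0.07, and this call was lost without 6 h replicate 1 (0.0989).

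The other lists were not called by camera between the times. Prostaglandin and eicosanoid genes had 8 of 20 lower and 3 higher, with Ptges at -0.56 ± 0.07. LPA receptor and metabolism genes had 4 of 12 lower and 3 higher, with Lpar1 at -1.88 ± 0.14, Lpar5 at 0.81 ± 0.12 and Lpar6 at 0.16 ± 0.05. The Lpar6 call (adjusted p = 0.0312, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) was lost without 2 h replicate 1 (0.0691), 2 h replicate 3 (0.112), 6 h replicate 1 (0.119) and 6 h replicate 2 (0.0874). Inflammatory cytokine genes had 12 of 27 lower and 8 higher, or 15 and 8 adjusted over the list alone, with the neutrophil chemoattractant gene Cxcl3 at -2.68 ± 0.15. Immunoregulatory and angiogenic genes had 11 of 25 lower and 7 higher, with Nrp1 at -0.71 ± 0.07 and Vegfa at -0.53 ± 0.11. LXR target genes had 9 of 18 lower and 5 higher, or 9 and 6 adjusted over the list alone, with Lpl at -1.04 ± 0.07. The SRF/MRTF and YAP list had 10 of 22 lower and 4 higher, or 10 and 5 adjusted over the list alone, with Filip1l at -0.57 ± 0.07. Type I interferon induction genes had 6 of 22 in each direction, with the Trex1 row at -1.12 ± 0.08. Unfolded protein response genes had 11 of 25 lower and 6 higher, with Sec61b at -0.45 ± 0.06. Glycolysis and hypoxia genes had 9 of 23 lower and 5 higher, with the glucose transporter gene Slc2a1 at -0.35 ± 0.04. Lysosome and phagocytosis genes had 9 of 24 higher and 3 lower, with Sqstm1 at -0.56 ± 0.07. For the pathway lists between the times, the counts adjusted over the list alone were the same where no separate count is given. The histone and nuclear RNA list had a median of 0.05 and a mean of 0.03 while camera gave the direction down. The plasmacytoid dendritic cell markers had 5 of 7 lower (camera adjusted p = 0.0518, and adjusted p = 0.508 with an estimated correlation). Camera called them at the preset correlation without 2 h replicate 1 (0.0378), 2 h replicate 2 (0.0357) or 6 h replicate 3 (0.0386). It also called them with thinned libraries (0.0413), with the replicate number as a block (0.027) and under total counts (0.0302). Total counts also called the inflammatory cytokine list (0.0438). Without 2 h replicate 2, 7425 genes changed and 46 interferon-stimulated genes were lower.

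**Figure D4:**
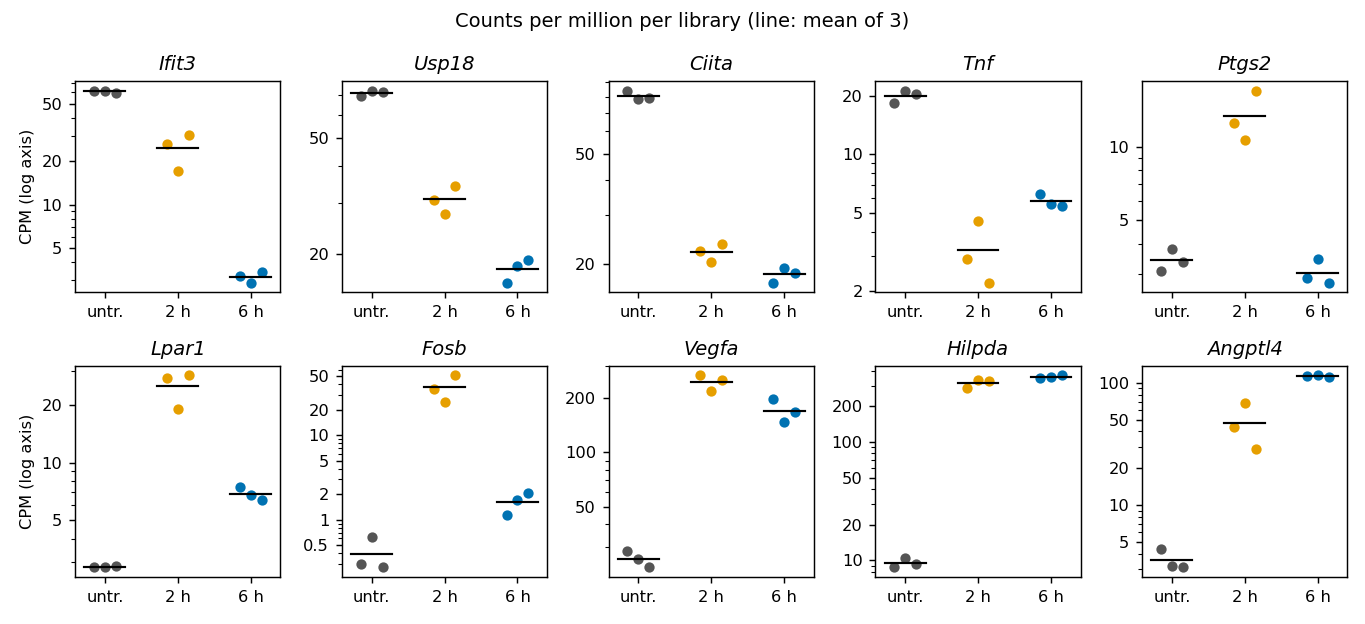
CPM of 10 genes in each library on a log axis, grouped as untreated, 2 h and 6 h, with a line at the mean of 3 libraries. Ifit3 falls from 60.9 CPM untreated to 24.5 at 2 h and 3.16 at 6 h, Hilpda rises from 9.43 to 316.7 and 357 CPM, and Ptgs2 goes from 3.42 to 13.4 and 3.04 CPM.

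The 2 h and 6 h responses were compared gene by gene. Hilpda, Lepr, Angptl4, Vegfa and Osm were higher at both times, and Usp18, Mx1, Ciita and Ccl2 lower at both. In all, 1759 genes were higher at both times and 1555 lower at both, against 730 and 708 expected of independent lists of these sizes. Unchanged groups simulated against shared controls gave a mean of 0.25 genes called in the same direction at both times over 20 simulations. With no gene changed few are called at all, so this is no baseline for lists of these sizes. The sign was the same in 69.6% of genes, against 66.6% simulated. In the other direction, 135 genes were higher at 2 h and lower at 6 h, and 154 lower at 2 h and higher at 6 h. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.65, against 0.49 simulated, with a covariance of 0.231 against 0.024 simulated. The 3 untreated libraries could not be divided so that each part kept 2. Part of the excess over independent lists may thus come from the shared controls. The simulation shared its controls in the same way, and its covariance was small beside that observed. Without 2 h replicate 2 the overlap was 3019 genes in place of 3314.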

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

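Tests chosen only after their result was seen were those on marked cell types, on time in culture and on low oxygen. The least squares and class-position tests were added later, with their readings set before the values were seen. For 6 h replicate 1 in the least squares test, the reading applied was stricter than the one set.

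Levels at 2 h and 6 h of LPA differed for 6991 genes by the direct test between the times, and for 81 of 98 named genes. Without untreated cells at each time, a change in the LPA effect cannot be told apart from time in culture or handling. Among them 289 genes were called in opposite directions at the 2 times with the difference itself called. Named genes of this kind were Cxcl3, with a log2 fold change of -2.68 from 2 h to 6 h after a rise from 191 to 393 CPM at 2 h, Sqstm1, at -0.56, Tk1, at -0.58, and Slc2a1, at -0.35. The rise of Tk1 at 2 h was lost without any 1 of 7 libraries, all but untreated replicate 2 and 2 h replicate 2 (adjusted p from 0.062 to 0.147, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The fall of Slc2a1 at 6 h was lost in the same test without untreated replicate 2 (0.0589), untreated replicate 3 (0.0502) or 6 h replicate 1 (0.0524).

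For each comparison of 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. Every other split puts libraries of both groups on each side, so a real difference adds to the spread within its sides. Few calls are then to be expected there, and the size of the gap does not measure the strength of the evidence. The real split, the 1 split of the 10 with as many genes in each comparison, gave 5525 genes at 2 h, where the highest other split gave 2. It gave 7472 genes at 6 h, where the highest other split gave 0, also among the 3 other splits that part all 3 same-numbered pairs as the real one does (the remaining 6 part 1 pair), and 6991 between the times, where the highest other gave 5.

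All 47 tested interferon-stimulated genes were lower at 6 h, with a median of -1.91. With all libraries thinned to equal depth 47 of these genes were lower. Random thinning leaves the expected CPM unchanged, so this count could hardly have moved and does not decide on depth. With total counts as the only scaling 47 were lower. That scaling moved the median of all genes at 6 h by 0.039 (log2). The choice between it and TMM thus does not account for a fall of this size. Loss of a marked cell type would lower its markers as far, and the lowest median of a marker list was -0.46, for T and NK cells. It stays open, because summed CPM of B and plasma cell markers fell from 11.6 to 2.41 and single macrophage and dendritic cell markers fell further than -1.91: Cx3cr1 by 2.63, Ccr2 by 2.53, Kmo by 3.16 and Itgae by 2.38. These single genes were picked, and Cd14 of the macrophage list rose. Macrophage and monocyte markers summed to 21010 CPM untreated and 21940 at 6 h, and conventional dendritic cell markers to 2776 and 2474. Interferon-stimulated genes summed to 4622 and 1472 CPM, so the sums of these marker lists do not show a loss of that size. Time in culture or handling cannot be told apart from LPA, because 0 untreated libraries have a time point of their own in the labels, so an effect of LPA on interferon signalling stays a hypothesis.

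Replicate 2 at 2 h lay towards the 6 h libraries. After thinning to equal depth its median position was 0.394, against 0.393 before. Random thinning leaves the expected CPM unchanged, so it could hardly have moved the position and does not decide on depth. RNA of 6 h cells mixed into this library may account for its position. Medians over genes that rise, fall or peak early were 0.045 apart, and least squares gave 6 h libraries a summed weight of 0.388 (95% interval 0.378 to 0.398). The position was not fully uniform, at 0.378 (0.371 to 0.386) for rising and 0.423 (0.408 to 0.445) for early-peaking genes, with intervals that do not overlap. The reading set beforehand went against 6 h replicate 1 as a source, since its weight (0.157) was below that of 6 h replicate 2 (0.231). Whether any such reads came from it was left open, because the interval of the difference (-0.07, interval -0.205 to 0.047) spans both signs. In the simulated mixture, made with 6 h replicate 1 alone, that library had a weight of 0.32 and the highest other 6 h library 0.05. The weights in the real library were not concentrated on any 6 h library in this way. A later effective time of harvest was not tested.

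Hilpda, Angptl4, Plin2 and Vegfa rose, a set that low oxygen can induce. Low oxygen stays open: the median of 19 hypoxia response genes was 0.13 at 6 h (95% interval -0.14 to 0.39), with 7 higher and 6 lower, and 0.11 at 2 h, with 7 higher and 0 lower (camera p = 0.0243, and 0.236 with an estimated correlation, unadjusted). Fatty acid sensing through PPAR nuclear receptors may account for the lipid genes of this set: 17 fatty acid oxidation genes regulated by PPAR had a median of 0.54 at 6 h (interval over genes 0.27 to 0.96), with 13 higher and 1 lower (camera p = 4.67e-06, but 0.129 with an estimated correlation, and 0.199 at 2 h, unadjusted). Among them Cpt1a, the gate of mitochondrial fatty acid import, rose from 126 to 312 CPM. Other lipid genes fell at 6 h, with Fabp4 at -1.30 and Lpl at -1.26 (log2) in the LXR target and lipid export list, where 5 rose and 11 fell. These falls run opposite to the rise of the fatty acid oxidation genes. The account therefore does not cover all lipid genes and stays a hypothesis. The hypoxia and fatty acid oxidation lists were written after the main results were seen, and LPA as the source of such a fatty acid was not tested.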

How the results depend on the processing

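Thinning to equal depth was added after seeing the data, and the other alternatives were planned. Across scaling, tool, filter, block, sample and depth alternatives, genes changed ran from 4865 to 6135 at 2 h, 6819 to 8044 at 6 h and 6408 to 7588 between the times, and interferon-stimulated genes lower from 31 to 38, 47 to 47 and 45 to 47. Against a 1.5-fold change, glmTreat called 564, 1149 and 399 genes, 10 interferon-stimulated genes at 2 h and an overlap of 304, and at an adjusted p of 0.01 there were 3646 genes at 2 h and an overlap of 2105. These alternatives ask for larger effects or stronger evidence by construction. Leaving out each library gave 4352 to 5580, 6226 to 7896 and 5767 to 7425 genes, 30 to 35, 47 to 47 and 46 to 46 interferon-stimulated genes, and an overlap of 2589 to 3664. Same-numbered libraries correlated at 0.09 to 0.18 at 2 h and 0.03 to 0.13 between the times, not all over the limit of 0.1. Different-numbered libraries correlated at -0.16 to 0.07 over all comparisons. At 2 h against untreated they correlated at -0.15 to -0.03, below every same-numbered pair of that comparison. Libraries correlated best with their own number in 6 of 6 cases at 2 h and in 4 of 6 between the times. Pairing there is thus hinted at by the data but not settled. With the number as a block 6135, 8036 and 7588 genes were called, the overlap was 3745, Cxcl10 passed at 2 h, and camera did not call the SRF/MRTF and YAP list at 2 h (0.0563) or the prostaglandin list at 6 h (0.0579) and called the plasmacytoid list between the times (0.027). The block changed no other call of a named gene or list. No named gene or list reversed under any alternative run. Of 132 called named results, glmTreat lost 39. The estimated correlation ended all 19 camera calls, and fry, which does not compare a list with other genes, added 33. Total counts gave 2557 higher and 2897 lower at 2 h, 4247 and 3212 at 6 h, and 4210 and 2912 between the times, and glmTreat 394 and 170, 508 and 641, and 32 and 367. Scaling moved the median of all genes by at most 0.053 (log2), under total counts between the times. Depth limits genes such as Ifnb1, which had at most 5 counts.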

Other observations

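The genes in these 2 paragraphs were chosen after their values were seen, and each rise or fall passed edgeR's quasi-likelihood test as in the report. Several genes of the fixed lists rose strongly at both times. The adhesive glycoprotein gene Thbs1 rose by 3.34 ± 0.22 and 2.98 ± 0.21 (log2 fold change ± SE, 2 h and 6 h), and the transglutaminase gene Tgm2 by 2.55 ± 0.14 and 3.31 ± 0.15. The LPS co-receptor gene Cd14 rose from 106 to 856 and 1078 CPM, and Arg2, an arginase gene, by 2.30 and 2.23. Cytokine genes diverged at 2 h, when Il1b rose by 3.20 and Il6 by 1.25 while Tnf fell by 2.59. Of the orphan nuclear receptors Nr4a1 rose by 3.29 and Nr4a2 by 2.35 at 2 h.

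Among other genes picked this way, Ccr2, the monocyte chemokine receptor gene, fell by 1.52 at 2 h and 2.53 at 6 h, and Cx3cr1, the fractalkine receptor gene, by 1.33 and 2.63. At 6 h Itgae, which encodes CD103, fell by 2.38 and the kynurenine pathway gene Kmo by 3.16. Enpp2, which encodes autotaxin, the enzyme that makes LPA, had a log2 fold change of -0.26 at 2 h that did not pass the test and fell by 2.16 at 6 h. In lipid metabolism Plin2, a lipid droplet coat gene, rose by 1.54 and 2.88, while the desaturase gene Scd2 fell by 0.60 and 1.44 and Elovl6 by 0.96 and 1.35.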
